A study of Homo sapiens with 6 samples.

How the data were processed

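Gene expression was measured on 1-colour Affymetrix arrays in TL-Om1 cells, an established human cell line of adult T-cell leukemia/lymphoma (ATL), a cancer of mature T cells. Cultures received the solvent DMSO or 100 nM of THZ1, a covalent inhibitor of the transcriptional kinase CDK7 that also binds CDK12 and CDK13, for 6 h. There were 3 arrays per group, and the labels call them biological triplicates. Groups and replicate numbers were taken from the sample titles.

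The deposited values are log2 expression values that the authors made with RMA, per the submitters' processing notes, which also name limma and give no versions. The chip definition, filters and any later step are not given in the sources used here. RMA subtracts background, brings the arrays close to 1 distribution and summarises the probes of a probe set, so a change shared by most transcripts is largely taken out before the values are written. The deposited log2 values ran from 1.37 to 13.8. Their medians over all 32321 probe sets were 5.48, 5.48 and 5.48 on DMSO arrays and 5.57, 5.52 and 5.55 on THZ1 arrays, so the medians were close without being equal. Over the genes used below, the 75th percentiles were 7.55, 7.56 and 7.54 on DMSO arrays and 7.20, 7.37 and 7.33 on THZ1 arrays. Medians over the genes below the median level were 4.55, 4.54 and 4.50 on DMSO arrays and 4.74, 4.66 and 4.73 on THZ1 arrays. The groups therefore differed in spread and not only by a constant. Scanner files were not used here, so the log2 scale and any centring of the table rest on the processing notes and the range of the values, and no detection call separated expressed from unexpressed genes. No depth exists for arrays; the 3 arrays per group limit the precision.

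Probe sets were named through the platform's annotation. Of the 32321 probe sets, 19158 carried 1 gene symbol, 1388 carried several and 11775 were unnamed here. Symbols were updated through Entrez IDs to the RefSeq gene table of assembly GRCh38.p14, in which 19128 of the probe sets with 1 symbol were found. Only probe sets with 1 symbol were used, with 1 probe set per gene, that with the highest mean over the 6 arrays, which left 18404 genes. Of the 637 genes with more than 1 such probe set, 17 had a probe set called higher and another called lower. No genome build is tied to the array's probes, so no coordinates are given. Gene lengths and overlapping genes come from the RefSeq table.

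THZ1 and DMSO arrays were compared with limma (lmFit and eBayes, two-sided, 14.0 degrees of freedom after moderation), with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p below 0.05, and 2-fold calls also needed an absolute log2 fold change of 1 or more. Fold changes are THZ1 minus DMSO, and errors are standard errors (SE) from limma with n = 3 arrays per group. The test, the 29 gene lists and most of the alternatives were fixed before the data were examined. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 29 lists, and again with the correlation estimated from the data and with fry. Members were also counted with p adjusted over the list alone. The ATL list was written from general knowledge of the disease, and work on these same cells cannot be excluded as a source of some members, so its direction is not independent evidence.

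The text names the 8 largest falls and 8 largest rises among called genes above the median level whose 2 groups of arrays did not overlap, passing over genes without a standard symbol, 17 genes fixed in advance (CDK7, CDK9, CDK12, CDK13, MYC, MCL1, IRF4, CCR4, IL2RA, TP73, BATF3, GATA3, RUNX1, MYB, NFKBIA, GAPDH and ACTB), and in each list up to 3 called members of the majority direction with the smallest adjusted p, up to 1 called member of the other direction and up to 1 member not called. Other names were chosen after their values were seen, and the text says so.

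Alternatives fixed in advance were the mean of all probe sets of a gene, leaving out the dimmest 33.3% of genes, quantile normalization applied again, cyclic loess, an intensity trend with robust estimation, array weights, the replicate number as a block, each array left out in turn, all named probe sets, and the other gene list tests. After seeing the data, a centring of each array on its median over the genes below the median level, a fit of the genes above the median level alone, and a fit of all probe sets were added. An alternative on added RNA controls, one on cross-hybridising probe sets and a check of RNA quality from control probe sets were planned and not run, because the numeric probe set IDs mark none of these.

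The fit was tested on simulated data with 200 changed genes among 18404. It recovered 42.0% of them at a log2 change of 0.5, 90.5% at 1 and 100% at 2, with 4, 7 and 8 false calls. The simulated genes varied independently, and no scale difference between the groups of arrays was put in. In the real data 8292 of the 18404 genes were called, so these rates do not carry over to the comparison of THZ1 with DMSO. R 4.3.3, limma 3.58.1 and the data.table package in version 1.17.8 were used, with Python 3.11.15 and matplotlib 3.10.9 for figures.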

Results

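The 6 arrays gave log2 expression levels of 18404 genes in TL-Om1 cells, a T-cell line from adult T-cell leukemia/lymphoma (ATL), after 6 h with DMSO (n = 3) or with 100 nM THZ1 (n = 3). THZ1 blocks CDK7, a kinase that phosphorylates RNA polymerase II early in transcription, and the comparison asks which transcripts change soon after that block. Across all probe sets, which are not independent replicates, DMSO arrays correlated with each other at r = 0.991 to 0.993, THZ1 arrays at 0.989 to 0.993, and arrays of different groups at 0.962 to 0.976.

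After 6 h of THZ1, MYC, a transcription factor that drives cell growth, fell by 1.97 on the log2 scale (SE 0.12, n = 3 per group) to 25.6% of its DMSO level, and PRDM1, a regulator of lymphocyte differentiation, fell by 2.12 (SE 0.09) to 23.0%. The lymphoid transcription factor IRF4 fell by 1.18 (SE 0.10) and the chemokine receptor CCR4 by 1.13, to 44.0% and 45.7% of their DMSO levels. Lower calls were made for 21 of 26 G2/M genes and for 19 of 25 homologous recombination and Fanconi genes, the latter 11 when quantile normalization was applied again, and neither list was called with an estimated correlation (adjusted p = 0.516 for each). Large rises were few and included the microRNA gene MIR21, the histone gene H3C3 and the early response gene IER3.

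Across the genome, limma with Benjamini-Hochberg adjustment called 8292 of the 18404 genes (45.1%), of which 4547 were higher and 3745 lower with THZ1, and 9892 genes had an unadjusted p below 0.05. At least 2-fold changes were nearly all falls, with 684 genes lower and 19 higher. These counts were 617 and 24 after cyclic loess, 544 and 29 when quantile normalization was applied again and 1068 and 11 after centring. The arrays of the 2 groups did not overlap for 10279 genes, where chance gives 10% of genes. Falls and rises lay at different expression levels. Among the 9202 genes above the median level, 3120 were lower and 1513 higher, with a median log2 change of -0.07, whereas among the 9202 genes below it 625 were lower and 3034 higher, with a median of 0.20. After centring on the genes below the median level, 299 of these 1513 rises and 520 of these 3034 rises were still called.

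The share of rises depended on the scaling of the arrays. They made up 54.8% of the calls on the values as deposited and 55.2% when quantile normalization was applied again (3918 higher, 3185 lower). The share was 42.3% after cyclic loess (2756 higher, 3759 lower) and 59.5% with array weights. It was 13.4% when each array was centred on its genes below the median level (819 higher, 5286 lower). That setting was chosen after seeing the data and lowers every THZ1 minus DMSO difference by 0.18, so it leaves a difference in spread between the groups in place. Changes are given below on the deposited scale. Without DMSO replicate 3, 2911 genes were higher and 3303 lower. The estimated array weights ran from 0.333 for THZ1 replicate 1 to 1.94 for THZ1 replicate 3. With 1 array left out, genes at least 2-fold lower numbered 577 (without THZ1 replicate 1) to 781 (without THZ1 replicate 2).

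**Figure D1:**
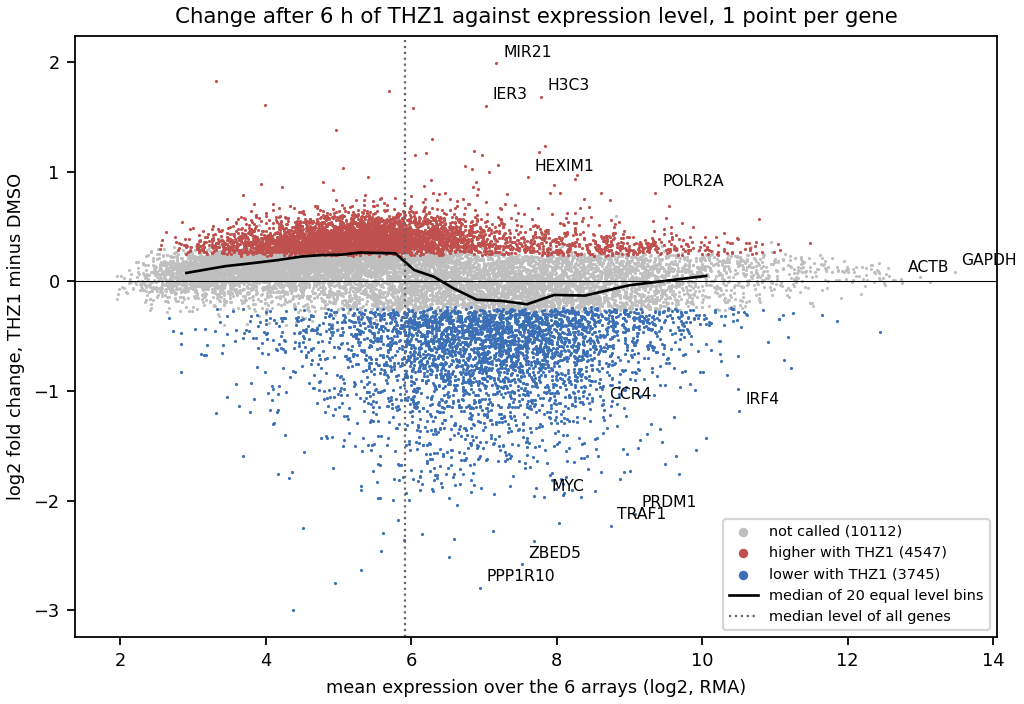
The log2 change after 6 h of THZ1 (vertical, THZ1 minus DMSO) against the mean log2 expression over the 6 arrays (horizontal), 1 point per gene, red for the 4547 genes called higher, blue for the 3745 called lower and grey for the rest, with the median of equal bins of level as a black line. The line lies above 0 below the median level (dotted) and mostly below 0 above it, and GAPDH and ACTB, which turn negative after cyclic loess or centring, were not called.

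The 8 largest falls among genes above the median level were in PPP1R10, ZBED5, MTFR2, DCP1B, LRIF1, ZFP62, E2F8 and TRAF1. PPP1R10, a regulatory subunit that targets protein phosphatase 1 in the nucleus, fell by 2.80 (SE 0.18) to 14.4% of its DMSO level, and ZBED5 fell by 2.58 (SE 0.12) to 16.7%. DCP1B, a cofactor of mRNA decapping, fell by 2.37 (SE 0.10), and E2F8, a cell-cycle repressor of the E2F family, fell by 2.27 (SE 0.14). TRAF1, an adaptor of TNF receptor signalling, fell by 2.23 (SE 0.10). The remaining 3 lay between MTFR2, which fell by 2.51, and ZFP62, which fell by 2.31. Each of these 8 had an adjusted p of 4.84e-08 or less with limma.

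The 8 largest rises above the median level were MIR21, H3C3, IER3, MIR142, H3C1, CCHCR1, H2AC14 and H2AC17, and each kept its call under every alternative. MIR21 rose by 1.99 (SE 0.11), to 397% of its DMSO level (adjusted p = 2.09e-08, limma), and MIR142 by 1.30 (SE 0.12). These microRNA genes lie within longer genes, MIR21 in VMP1 and MIR142 in MIR142HG, so their probe sets can also read precursor or host transcripts. The replication-dependent histone genes H3C3, H3C1, H2AC14 and H2AC17 rose by 1.68 (SE 0.09), 1.24 (SE 0.13), 1.18 (SE 0.17) and 1.17 (SE 0.13). IER3, a stress-induced survival gene, rose by 1.60 (SE 0.11). CCHCR1 rose by 1.19 (SE 0.15) on its brighter probe set, while its other probe set changed by 0.03 (SE 0.09) and was not called.

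Surface and identity genes of ATL cells were mostly lower. In that list 10 of 19 measured members fell and 2 rose, with the same counts adjusted over the list alone, and the list lay below other genes (camera adjusted p = 0.00146, and adjusted p = 0.516 with an estimated correlation). After centring 11 were lower and 1 higher. The list draws on earlier work on this disease and is not independent of it. The chemokine receptors CCR8 and CCR7, which guide T cells to skin and lymph nodes, each fell by 1.43 (SE 0.09 and 0.10), and the adhesion molecule ICAM1 fell by 1.60 (SE 0.11). IL2RA, the interleukin receptor chain CD25 of activated T cells, fell by 0.79 (SE 0.11) to 57.7% of its DMSO level, TP73 of the p53 family by 0.53 (SE 0.09), and BATF3 by 0.42 (SE 0.10). TNFRSF4, the OX40 costimulatory receptor, rose by 0.46 (SE 0.09), whereas FOXP3, the regulatory T-cell factor, differed by 0.22 (SE 0.10) and was not called. Array weights alone called FOXP3 (adjusted p = 0.0372, with up to 0.802 in other alternatives).

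Transcription factors of the T-cell lineage followed the same direction, with 13 of 25 members lower and 5 higher (13 and 6 adjusted over the list alone; camera adjusted p = 0.00290, and adjusted p = 0.516 with an estimated correlation). FLI1 fell by 1.57 (SE 0.09), MYB by 1.01 (SE 0.10), GATA3 by 0.68 (SE 0.10) and RUNX1 by 0.45 (SE 0.09), although the call for RUNX1 was lost when quantile normalization was applied again. TBX21, the T-bet factor of type 1 helper cells, rose by 0.36 (SE 0.10), with no call after cyclic loess (adjusted p = 0.0548), and no member was called higher after centring. STAT5B was not called at 0.30 (SE 0.12, 0.19 to 0.44 with 1 array left out) but was called without THZ1 replicate 2 (adjusted p = 0.00579). 3 of the 13 alternatives called STAT5B, over which its adjusted p ran from 0.00579 to 0.592.

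Of 19 T-cell receptor signalling genes 6 fell and 5 rose (7 and 5 adjusted over the list alone; camera adjusted p = 0.247), with 8 lower and 2 higher after centring. The adaptor LCP2 fell by 1.22 (SE 0.10), the adhesion receptor CD2 by 1.32 (SE 0.11) and the paracaspase MALT1 by 0.99 (SE 0.09), while the calcium-responsive factor NFATC1 rose by 0.58 (SE 0.11). VAV1 was not called at -0.26 (SE 0.10) but was called without THZ1 replicate 3 (adjusted p = 0.0221). 4 of the 15 alternatives called VAV1, over which its adjusted p ran from 0.00348 to 0.299. Among 23 NF-kB target genes 9 fell and 7 rose (10 and 7 adjusted over the list alone; camera adjusted p = 0.136), with 11 lower and 3 higher after centring. TRAF1 and ICAM1 led the falls, TNFAIP3 and NFKBIA, which restrain NF-kB, fell by 0.92 (SE 0.09) and 0.68 (SE 0.10), and IER3 rose. TNIP1 was not called at -0.23 (SE 0.10). 4 of the 15 alternatives called TNIP1, over which its adjusted p ran from 0.00474 to 0.877. Of 25 immediate early genes 10 rose and 4 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.271), but 5 were called higher and 6 lower after centring. In that list IER2 rose by 0.92 (SE 0.12) the phosphatase gene DUSP2 rose by 0.58 (SE 0.10), and MYC fell as given above. KLF6 was not called at 0.26 (SE 0.11, 0.17 to 0.34 with 1 array left out) but was called without THZ1 replicate 2 (adjusted p = 0.0281). 5 of the 15 alternatives called KLF6, over which its adjusted p ran from 0.0193 to 0.639, and its change was 0.39 and called when quantile normalization was applied again.

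**Figure D2:**
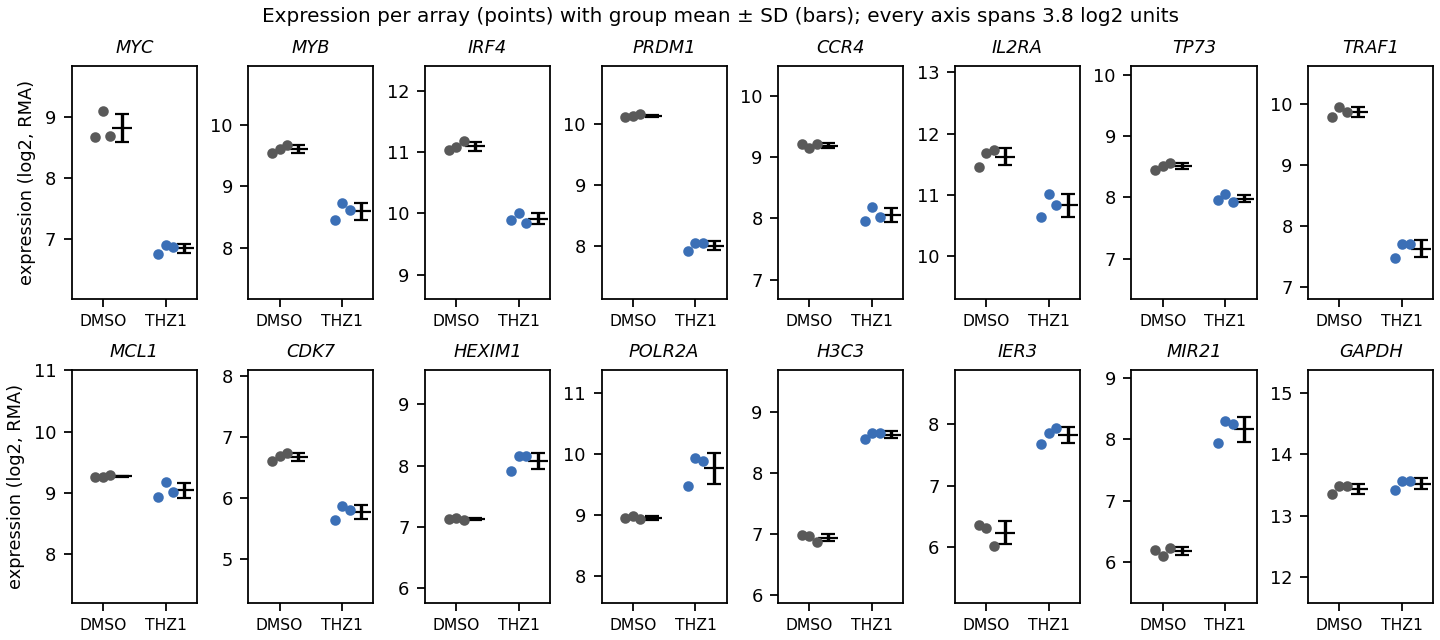
Log2 expression on each of the 3 DMSO arrays (grey) and 3 THZ1 arrays (blue) for 16 genes, with the group mean and SD as bars and every vertical axis spanning the same log2 distance. The THZ1 arrays lie below every DMSO array for MYC, MYB, IRF4, PRDM1, CCR4, IL2RA, TP73, TRAF1, MCL1 and CDK7 and above every DMSO array for HEXIM1, POLR2A, H3C3, IER3 and MIR21, MCL1 was not called, and GAPDH, which turns negative after cyclic loess or centring, overlaps.

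The G2/M, homologous recombination and Fanconi, and G1/S lists had falls and no called rise on the deposited scale, with 5, 6 and 14 members not called. After cyclic loess and when quantile normalization was applied again, 2 G2/M genes were called higher, and 19 and 18 lower. Of the 26 G2/M genes 21 fell, 24 after centring, with 21 also adjusted over the list alone (camera adjusted p = 1.62e-08, and adjusted p = 0.516 with an estimated correlation). The mitotic kinase gene AURKA fell by 1.29 (SE 0.09), TTK fell by 1.12 (SE 0.10) and the checkpoint gene BUB1B fell by 1.24 (SE 0.11). CCNB2 was not called at -0.21 (SE 0.11, -0.27 to -0.11 with 1 array left out). 1 of the 15 alternatives called CCNB2, over which its adjusted p ran from 0.0132 to 0.344. Homologous recombination and Fanconi genes numbered 19 falls among 25, also 19 adjusted over the list alone (camera adjusted p = 1.62e-08, and adjusted p = 0.516 with an estimated correlation). PALB2, the partner of BRCA2, fell by 2.04 (SE 0.10) to 24.3% of its DMSO level, RAD51C by 1.32 (SE 0.10) and FANCM by 1.28 (SE 0.10), with XRCC3 not called at -0.18 (SE 0.10, -0.25 to -0.12 with 1 array left out), but called after centring (-0.36, adjusted p = 0.0124). The homologous recombination list had 21 falls after centring, 14 after cyclic loess and 11 when quantile normalization was applied again, and no rise in any of them.

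Of 27 genes for the G1/S transition and DNA replication, 13 fell and none rose (14 and 0 adjusted over the list alone; camera adjusted p = 1.36e-05, and adjusted p = 0.516 with an estimated correlation). The falls and rises were 17 and 0 after centring, 12 and 1 after cyclic loess and 11 and 3 when quantile normalization was applied again. The clamp loader subunit RFC4 fell by 1.53 (SE 0.11), the replication licensing factor CDC6 by 1.57 (SE 0.11) and the cyclin gene CCNE2 by 1.24 (SE 0.10). RRM2 was not called at -0.26 (SE 0.10) but was called without THZ1 replicate 2 (adjusted p = 0.0359). 6 of the 15 alternatives called RRM2, over which its adjusted p ran from 0.00494 to 0.240. D-type cyclins and CDK inhibitors had 4 of 15 higher and 3 lower, as also adjusted over the list alone (camera adjusted p = 0.495), and 3 higher and 6 lower after centring. After cyclic loess, and when quantile normalization was applied again, 5 were higher and 3 lower. CDKN2B, CCND1 and CDKN1C rose by 0.49 (SE 0.09), 0.56 (SE 0.12) and 0.50 (SE 0.13), and RBL1 fell by 0.80 (SE 0.10). CDKN2A was not called at 0.21 (SE 0.10, 0.12 to 0.26 with 1 array left out). 2 of the 15 alternatives called CDKN2A, over which its adjusted p ran from 0.00717 to 0.890, and its change was 0.39 when quantile normalization was applied again and 0.30 after cyclic loess, both called.

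Transcripts of the kinases that THZ1 binds were lower. CDK7 fell by 0.90 (SE 0.10) to 53.5% of its DMSO level, CDK12 by 0.68 (SE 0.12) and CDK13 by 0.58 (SE 0.11). CDK9, the kinase of the elongation factor P-TEFb and not among these, fell by 0.50 (SE 0.10). Among 19 transcriptional kinases and partners 10 fell and 4 rose, as also adjusted over the list alone (camera adjusted p = 0.00927, and adjusted p = 0.579 with an estimated correlation), a call lost when dim genes were left out, when quantile normalization was applied again and after cyclic loess. After centring 13 of them were lower and 1 higher. All 19 lay above the median level, so leaving out dim genes changed only the genes they are compared with. MEPCE, which caps and stabilises the 7SK RNA, fell by 0.95 (SE 0.10), and HEXIM1, the 7SK-bound inhibitor of P-TEFb, rose by 0.95 (SE 0.10) to 193% of its DMSO level. AFF1 was not called at -0.16 (SE 0.11, -0.23 to -0.05 with 1 array left out), with a positive sign when quantile normalization was applied again. 1 of the 15 alternatives called AFF1, over which its adjusted p ran from 0.0334 to 0.968. Of 27 genes of the general RNA polymerase II machinery 10 fell and 4 rose, as also adjusted over the list alone (camera adjusted p = 0.0723), but 6 fell and 10 rose when quantile normalization was applied again, and the median of -0.12 turned positive then and after cyclic loess, while centring gave 14 falls and 2 rises. Without THZ1 replicate 2 this list was called (adjusted p = 0.0416). The initiation factor genes GTF2E1, GTF2H1 and TBP fell by 2.36 (SE 0.10), 1.29 (SE 0.10) and 1.09 (SE 0.12), whereas POLR2A, which encodes the largest polymerase subunit, rose by 0.81 (SE 0.12). POLR2L was not called at 0.21 (SE 0.10). 2 of the 15 alternatives called POLR2L, over which its adjusted p ran from 0.0302 to 0.849.

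Falls were called among genes that block cell death and among genes that promote it. Of 11 anti-apoptotic genes 6 fell and none rose (8 and 0 adjusted over the list alone; camera adjusted p = 0.00777, and adjusted p = 0.535 with an estimated correlation), a call lost in fits without dim genes. The falls and rises were 6 and 1 after cyclic loess, 5 and 1 when quantile normalization was applied again and 9 and 0 after centring. Of the 11 genes 10 lay above the median level, so the fits without dim genes removed mostly genes outside the list. CFLAR, an inhibitor of death receptor signalling, fell by 1.18 (SE 0.13), BCL2L1 by 0.60 (SE 0.10) and BIRC2 by 0.58 (SE 0.10). MCL1, the short-lived survival protein often followed under transcriptional inhibitors, was not called at -0.23 (SE 0.10, adjusted p = 0.0666 with limma, 0.00553 to 0.202 over the alternatives), and 6 of the 15 alternatives called it, among them the fit without THZ1 replicate 2 (0.0334). XIAP was not called at -0.50 (SE 0.19), a value that rested on single arrays. 7 of the 15 alternatives called XIAP, over which its adjusted p ran from 0.00524 to 0.225. XIAP was -0.20 without THZ1 replicate 1, and it was called without DMSO replicate 2 (-0.59, adjusted p = 0.0392) or THZ1 replicate 3 (-0.72, adjusted p = 0.00593). Of 18 pro-apoptotic genes 7 fell and 3 rose (7 and 4 adjusted over the list alone; camera adjusted p = 0.192), with a median of 0.02, negative in every rescaling, a mean of -0.17 and a downward test, and 8 lower and 1 higher after centring. The death receptor genes TNFRSF10B and TNFRSF10A and the apoptosome gene APAF1 fell by 0.97 (SE 0.10), 0.86 (SE 0.12) and 0.91 (SE 0.11), and HRK rose by 0.52 (SE 0.10). BIK was not called at 0.27 (SE 0.11) but was called without DMSO replicate 1 (adjusted p = 0.0187) or THZ1 replicate 2 (0.0422). 4 of the 13 alternatives called BIK, over which its adjusted p ran from 0.0173 to 0.671. Target genes of p53 had 10 falls and 2 rises among 21, as also adjusted over the list alone (camera adjusted p = 0.00251, and adjusted p = 0.516 with an estimated correlation), again lost in fits without dim genes, with 13 lower and none higher after centring. Here 18 of the 21 lay above the median level. The translesion polymerase gene POLH fell by 1.26 (SE 0.09) and MDM2, the ubiquitin ligase of p53, by 0.96 (SE 0.10). ZMAT3 rose by 0.37 (SE 0.11), with no call after centring, without DMSO replicate 3 (adjusted p = 0.0704) or without THZ1 replicate 2 (0.0570). PLK3 was not called at -0.23 (SE 0.11, -0.33 to -0.14 with 1 array left out) but was called without DMSO replicate 3 (adjusted p = 0.0359). 2 of the 15 alternatives called PLK3, over which its adjusted p ran from 0.00740 to 0.365.

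Among 23 ribosome biogenesis and MYC target genes 9 fell and 2 rose, as also adjusted over the list alone (camera adjusted p = 0.00251, and adjusted p = 0.516 with an estimated correlation), with the call lost in fits without dim genes and 14 lower and none higher after centring. All 23 lay above the median level, so leaving out dim genes changed only the genes they are compared with. NOP16, POLR1B and BYSL fell by 1.21 (SE 0.09), 1.13 (SE 0.12) and 0.85 (SE 0.09). NOLC1 rose by 0.29 (SE 0.10), with no call after centring, without DMSO replicate 1 or 2 (adjusted p = 0.118 and 0.0812) or without THZ1 replicate 2 or 3 (0.0806 and 0.0742). TSR1 was not called at -0.22 (SE 0.10), a value that is 0.00 when quantile normalization is applied again. 1 of the 15 alternatives called TSR1, over which its adjusted p ran from 0.00612 to 0.977. Of 38 cytosolic ribosomal protein genes 5 rose and none fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.00972, and adjusted p = 0.533 with an estimated correlation), and their median of 0.16 became -0.02 after centring, when neither a member nor the list was called. RPL19, RPLP2 and RPL23 rose by 0.44 (SE 0.10), 0.29 (SE 0.09) and 0.26 (SE 0.09), none of them called after centring. The call for RPLP2 was lost without DMSO replicate 1, 2 or 3 (adjusted p = 0.0540, 0.0646 and 0.0527) and that for RPL23 without DMSO replicate 1, 2 or 3 (0.0959, 0.0913 and 0.0796) or THZ1 replicate 3 (0.144). RPL7A was not called at 0.31 (SE 0.12, 0.18 to 0.44 with 1 array left out) but was called without DMSO replicate 3 (adjusted p = 0.0127). 6 of the 15 alternatives called RPL7A, over which its adjusted p ran from 0.0127 to 0.480.

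Of 29 oxidative phosphorylation genes 9 rose and none fell, as also adjusted over the list alone (camera adjusted p = 0.0286, and adjusted p = 0.579 with an estimated correlation), and their median of 0.18 became 0.00 after centring, with 1 rise and 2 falls, whereas 12 rose after cyclic loess and 14 when quantile normalization was applied again. The list was not called after centring, without DMSO replicate 1 (adjusted p = 0.0578) or without THZ1 replicate 2 (0.0793). Genes of respiratory complex I led, NDUFB8, NDUFB9 and NDUFA1 rising by 0.51 (SE 0.09), 0.43 (SE 0.10) and 0.38 (SE 0.09), of which only NDUFB8 was called after centring. NDUFA2 was not called at 0.27 (SE 0.12, 0.16 to 0.40 with 1 array left out) but was called without THZ1 replicate 1 (adjusted p = 0.00938). 6 of the 15 alternatives called NDUFA2, over which its adjusted p ran from 0.00320 to 0.641, and its change was 0.50 when quantile normalization was applied again and 0.42 after cyclic loess, both called. In the list of 19 glycolysis genes 3 rose and 2 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.919), with 5 lower and none higher after centring, but 6 higher and 2 lower after cyclic loess and when quantile normalization was applied again. The glucose transporter gene SLC2A1 fell by 1.05 (SE 0.11), and ALDOC, PFKFB3 and GPI rose by 0.28 (SE 0.09), 0.34 (SE 0.12) and 0.26 (SE 0.10) with no call after centring. The calls were also lost for ALDOC without DMSO replicate 2 or 3 (adjusted p = 0.0815 and 0.0895), for PFKFB3 after cyclic loess, when quantile normalization was applied again, without DMSO replicate 2 (0.157, when it differed by 0.22) or THZ1 replicate 1 (0.106), and for GPI without DMSO replicate 1, 2 or 3 (0.167, 0.0552 and 0.0856) or THZ1 replicate 2 or 3 (0.127 and 0.107). PGK1 was not called at 0.24 (SE 0.10) but was called without THZ1 replicate 1 (adjusted p = 0.0205). 7 of the 15 alternatives called PGK1, over which its adjusted p ran from 0.0120 to 0.712, and its change was 0.22 and called after cyclic loess.

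Of 20 genes of the unfolded protein and integrated stress responses 9 fell and 1 rose, as also adjusted over the list alone (camera adjusted p = 0.00438, and adjusted p = 0.516 with an estimated correlation), a call lost in fits without dim genes, with 10 lower and 1 higher after centring. Above the median level lay 18 of the 20, so those fits removed mostly genes outside the list. HERPUD1, which acts in degradation from the endoplasmic reticulum, fell by 1.74 (SE 0.12) to 29.9% of its DMSO level, the stress transcription factor XBP1 by 1.05 (SE 0.11) and DDIT4 by 1.03 (SE 0.09), while CHAC1 rose by 0.55 (SE 0.12). SLC7A11 was not called at 0.25 (SE 0.11, 0.16 to 0.37 with 1 array left out) but was called without THZ1 replicate 1 (adjusted p = 0.00917). 5 of the 15 alternatives called SLC7A11, over which its adjusted p ran from 0.00917 to 0.720, and its change was 0.36 when quantile normalization was applied again and 0.32 after cyclic loess, both called. Among 16 heat shock protein genes 3 fell and 2 rose, as also adjusted over the list alone (camera adjusted p = 0.508), with a median of 0.03, negative after cyclic loess and centring, a mean of -0.08 and a downward test, and 6 lower and none higher after centring, but 3 higher and 2 lower after cyclic loess. DNAJB1 fell by 1.17 (SE 0.14), HSPA8 by 0.46 (SE 0.09) and DNAJA1 by 0.31 (SE 0.10). HSPB1 rose by 0.31 (SE 0.10), with no call after centring or without DMSO replicate 1 or 3 (adjusted p = 0.0526 and 0.0678). HSPA6 was not called at 0.20 (SE 0.11, 0.12 to 0.30 with 1 array left out), with a negative sign after cyclic loess. The call for DNAJA1 was lost after cyclic loess and without DMSO replicate 2 or 3 (adjusted p = 0.0512 and 0.117) or THZ1 replicate 2 or 3 (0.0707 and 0.0508).

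Of 24 interferon response genes 6 fell and 4 rose, as also adjusted over the list alone (camera adjusted p = 0.410), with 9 lower and 2 higher after centring. XAF1, IRF1 and CXCL10 fell by 0.84 (SE 0.09), 0.58 (SE 0.12) and 0.55 (SE 0.11), and IFI6 rose by 0.51 (SE 0.09). ISG15 was not called at 0.23 (SE 0.11, 0.10 to 0.32 with 1 array left out). 1 of the 15 alternatives called ISG15, over which its adjusted p ran from 0.0337 to 0.816, and its change was 0.34 and called when quantile normalization was applied again. Cytokine and chemokine genes had 10 rises and 2 falls among 27, as also adjusted over the list alone (camera adjusted p = 0.148), but 2 rises and 3 falls after centring and 5 and 2 after cyclic loess, when their median of 0.17 became -0.02 and 0.00. LTB, TNF and CCL17 rose by 0.46 (SE 0.09), 0.52 (SE 0.11) and 0.42 (SE 0.10), with CCL17 not called after centring, whereas TNFSF10, which encodes the death ligand TRAIL, fell by 0.92 (SE 0.10). IL15 was not called at -0.22 (SE 0.11, -0.30 to -0.11 with 1 array left out) but was called without THZ1 replicate 1 (adjusted p = 0.0396). 4 of the 13 alternatives called IL15, over which its adjusted p ran from 0.00582 to 0.373, and its change was -0.38 when quantile normalization was applied again and -0.41 after cyclic loess, both called.

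The ZNF family of zinc finger genes, most of them DNA-binding transcription factors, had 185 falls and 45 rises among 439 measured members (186 and 47 adjusted over the list alone; camera adjusted p = 3.13e-08, and adjusted p = 0.331 with an estimated correlation). The falls and rises numbered 228 and 6 after centring and 203 and 19 after cyclic loess. ZNF557 fell by 1.97 (SE 0.09) to 25.5% of its DMSO level, ZNF766 by 1.80 (SE 0.10) and ZNF672 by 1.61 (SE 0.09), while ZNF580 rose by 0.71 (SE 0.10). ZNF814 was not called at -0.40 (SE 0.21), and its value was -0.11 without THZ1 replicate 3, -0.22 without DMSO replicate 3 and -0.56 without THZ1 replicate 1. 2 of the 13 alternatives called ZNF814, over which its adjusted p ran from 0.0148 to 0.602. Of 16 replication-dependent histone genes in the list fixed in advance 5 rose and 2 fell, as also adjusted over the list alone (camera adjusted p = 0.207), and their median of 0.14 became -0.04 after centring, with 2 rises and 3 falls. There were 8 rises after cyclic loess (2 falls) and when quantile normalization was applied again (1 fall). H2BC21, H2BC8 and H2BC6 rose by 0.93 (SE 0.10), 0.61 (SE 0.10) and 0.38 (SE 0.09), with H2BC6 not called after centring, and H2AC6 fell by 0.36 (SE 0.09) with no call when quantile normalization was applied again. H4C2 was not called at -0.23 (SE 0.10) but was called without THZ1 replicate 2 (adjusted p = 0.0357). 6 of the 15 alternatives called H4C2, over which its adjusted p ran from 0.00480 to 0.148.

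**Figure D3:**
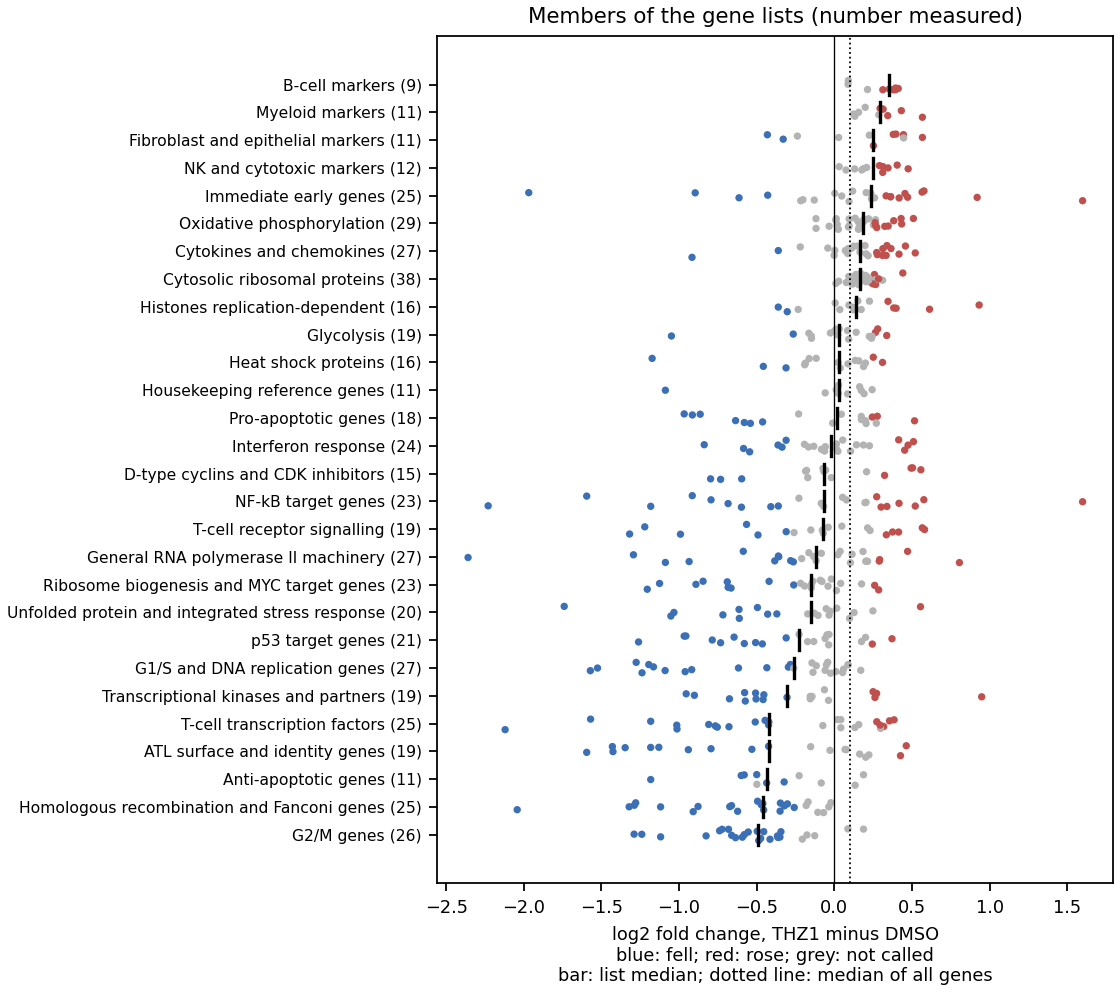
The log2 change (horizontal, THZ1 minus DMSO) of each measured member of the gene lists, without the zinc finger family, 1 point per gene with fallen members in blue, risen members in red and members not called in grey, ordered by the list median (bar). The medians run from -0.49 for G2/M genes to 0.35 for B-cell markers, and the medians of ribosomal protein, cytokine, histone, glycolysis, heat shock, housekeeping and pro-apoptotic genes turn negative after centring.

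Markers of other cell types, most of them dim in these cells, were often called higher on the deposited scale and seldom after centring. Rises were called in 6 of 9 B-cell markers (6 adjusted over the list alone; camera adjusted p = 0.0437, and adjusted p = 0.516 with an estimated correlation), 6 of 11 myeloid markers (7 adjusted over the list alone; camera adjusted p = 0.0245, and adjusted p = 0.516 with an estimated correlation) and 6 of 12 NK and cytotoxic markers (6 adjusted over the list alone; camera adjusted p = 0.0640), with no falls. Among 11 fibroblast and epithelial markers 5 rose and 2 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.320). CD79B, CD79A and PAX5 rose by 0.39 (SE 0.10), 0.41 (SE 0.11) and 0.38 (SE 0.11), CD14 and ELANE each by 0.31 (SE 0.09 and 0.10) and CD68 by 0.57 (SE 0.10), and NKG7, CD8A and CD8B by 0.48 (SE 0.11), 0.40 (SE 0.12) and 0.31 (SE 0.10). KRT19, COL1A1 and COL3A1 rose by 0.57 (SE 0.11), 0.44 (SE 0.10) and 0.40 (SE 0.09), and PDGFRB fell by 0.43 (SE 0.11) with no call when quantile normalization was applied again. After centring, no B-cell or NK and cytotoxic marker, 1 myeloid marker (CD68) and 1 fibroblast and epithelial marker (KRT19) was called higher. B-cell, myeloid and NK and cytotoxic markers had 1, 2 and 1 rises after cyclic loess and 1, 2 and 2 when quantile normalization was applied again. CD79A, PAX5, CD14 and CD8B lost their calls under both of these, CD8A after cyclic loess, and CD8B with the mean of its probe sets (adjusted p = 0.0933). Calls were also lost without DMSO replicate 1 (CD14, adjusted p = 0.0610), DMSO replicate 2 (ELANE, CD8A and CD8B, 0.0638, 0.0733 and 0.0989), DMSO replicate 3 (CD79A and ELANE, 0.0564 and 0.0678), THZ1 replicate 1 (CD8A, 0.0609), THZ1 replicate 2 (ELANE, 0.0521) and THZ1 replicate 3 (CD14 and CD8B, 0.0641 and 0.0968). The B-cell list was not called without DMSO replicate 2 or 3 (0.0581 and 0.0543) or THZ1 replicate 1 (0.0942), nor the B-cell and myeloid lists after cyclic loess, whereas the NK and cytotoxic list was called without DMSO replicate 1 (0.0314) or THZ1 replicate 2 (0.0406). Not called were BLK at 0.21 (SE 0.12, 0.11 to 0.30 with 1 array left out), AIF1 at 0.29 (SE 0.12), KRT18 at 0.45 (SE 0.18) and GNLY at 0.21 (SE 0.11, 0.11 to 0.27 with 1 array left out), the last negative after cyclic loess. AIF1 was called without DMSO replicate 1 (adjusted p = 0.0195) or THZ1 replicate 2 (0.0488), and KRT18 without THZ1 replicate 3 (0.68, adjusted p = 0.00266), while without THZ1 replicate 1 KRT18 differed by 0.19. AIF1 was called in 4 of 13 alternatives (adjusted p from 0.00949 to 0.528), KRT18 in 5 of 15 (0.00266 to 0.282, and 0.67 when quantile normalization was applied again) and BLK in 1 of 14 (0.0326 to 0.931).

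Housekeeping genes gave 1 call among 11, the fall of TBP given above (1 adjusted over the list alone; camera adjusted p = 0.919), with a median of 0.03, negative after cyclic loess and centring, a mean of -0.02 and an upward test. After cyclic loess, and also when quantile normalization was applied again, 4 of the 11 rose and 1 fell. GAPDH differed by 0.08 (SE 0.10, 0.04 to 0.14 with 1 array left out) and ACTB by 0.03 (SE 0.10), neither was called, and both turned negative after cyclic loess (-0.16 and -0.16), ACTB also when quantile normalization was applied again or without DMSO replicate 1 or THZ1 replicate 2, and after centring (-0.10 and -0.16).

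Camera called 15 of the 29 lists at its preset correlation and none with the correlation estimated from the data, where each estimate rests on 6 arrays. Without a measure of total RNA per cell, the values give each transcript relative to the rest of its array.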

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

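The comparisons above rest on probe sets with 1 gene name. A fit of all probe sets, chosen after seeing the data, also called differences among the probe sets outside them. Of the 11775 probe sets without a gene name here, 791 were at least 2-fold lower and 58 at least 2-fold higher with THZ1. Of the 1388 probe sets that carry several genes, 47 were at least 2-fold lower. The 2-fold falls made up 6.72% of the unnamed probe sets, 3.39% of those with several genes and 3.72% of the 19158 with 1 gene. Probe set 7896279 went from a mean log2 value of 7.42 to 2.44 (change -4.98, SE 0.22, limma adjusted p = 3.94e-05) and 7893703 from 8.24 to 3.46 (change -4.78, SE 0.34), while 8015796 and 7900652 were higher by 1.99 (SE 0.13) and 2.24 (SE 0.29). What these probe sets measure, including any array controls among them, is not known here. Their rate of 2-fold falls may therefore not be comparable with that of probe sets with 1 gene.

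The tests of the 3 patterns below were chosen after their results were seen, except the tests of short gene classes and of matched lists, which were set out first. The first pattern is that most calls among genes below the median level were rises (3034 against 625 falls), of which 520 were still called after centring. A scale shift between the groups of arrays may account for these rises: 26 markers of B cells, myeloid cells, fibroblasts and epithelium below the median level had a median change of 0.300 (95% interval 0.206 to 0.379), against 0.196 for the other dim genes. The difference between these medians only just exceeded the limit of 0.1 set for calling them alike, so a scale shift and a true rise of dim transcripts cannot be told apart for them. The other dim genes were not matched to the markers on level. Against random lists matched on level and length, the whole marker lists lay within the range of 95% of random medians. The medians were 0.354 (0.036 to 0.357) for B-cell, 0.294 (0.051 to 0.360) for myeloid and 0.252 (-0.207 to 0.286) for fibroblast and epithelial markers. Genes chosen as at least 2-fold higher on 2 arrays per group (18 to 24 genes) had a median change of 1.02 to 1.35 on the arrays left out, over 9 choices. All genes below the median level had a median change of 0.11 to 0.25 on the same arrays. As a set, the chosen genes thus rose by more than the dim genes did. The arrays left out carry any shift that their groups share, so this test cannot decide on a shift as a cause. Of the 19 genes at least 2-fold higher on all arrays, 14 lay above the median level and 5 below it. An effect of THZ1 on dim transcripts stays open.

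A second pattern is that longer genes fell more. Across the 9196 genes above the median level with a length, which are not independent replicates, the log2 change dropped with the log10 of gene length in GRCh38.p14 (slope -0.196, 95% interval -0.209 to -0.184). The median change was 0.23 in the shortest of 10 length groups (median length 1.88 kb), -0.25 in a group of 64.1 kb and -0.17 in the longest (208 kb), so the trend is not a steady one. Expression level does not account for it, as the slope was -0.186 with level as a smooth covariate, nor do short gene classes, as it was -0.199 in protein-coding genes without histone and ribosomal protein genes. An effect of THZ1 on long transcription units remains a hypothesis, and RNA stability, which goes with gene length in unknown measure here, was not tested.

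A further pattern is the fall of whole lists. Level and length do not account for 4 of them, compared with 10000 random lists matched on both: the share of random medians at or below the list's was 1e-04 for G2/M genes and 1e-04 for the ZNF family, the smallest the draws can give, 2e-04 for ATL surface and identity genes and 0.002 for homologous recombination and Fanconi genes. Over all 29 lists only these 4 and the T-cell transcription factors had an adjusted value below 0.05 (0.0029, 0.0029, 0.00387, 0.0232 and 0.0058). Members of a list vary together, so these shares describe these arrays, and a direct effect of THZ1 on these genes may be a source but was not separated from effects through MYC or other regulators.

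Whether another division of the 6 arrays could give such results was counted over all 10 splits into 3 and 3, which are too few for a share under 0.05. In 1 of the 10, the real one, 8292 genes were called, against 0 in each other split. The 2-fold count was 703 in the real split, again 1 of the 10, and 0 at most in the others. Every other split mixes DMSO and THZ1 arrays, so the difference between the groups adds to the spread on each side and few calls are likely. These gene counts therefore cannot tell an effect of THZ1 from any other difference shared by the arrays of a group. For gene lists the real split called 15, 1 of the 10 as large, and another split called 13, so camera's preset correlation calls lists on mixed groups too.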

How the results depend on the processing

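The alternatives named in the methods were planned, except the centring on dim genes, the fit of genes above the median level and the fit of all probe sets, which were chosen after seeing the data. The planned shift on added RNA controls and the removal of cross-hybridising probe sets were not run, and signal over background could not be judged without detection calls. The cause of a change was not tested unless a sentence gives it. The count of genes called lower stayed within 1.5 times its value of 3745 in every alternative. Genes higher numbered 2756 after cyclic loess and 819 after centring, and 2911 (without DMSO replicate 3) to 4284 with 1 array left out. Centring gave 1079 genes changed at least 2-fold, 1068 lower and 11 higher, repeated quantile normalization 29 higher at least 2-fold, and the fit above the median level 5073 called and 1759 higher, from fewer genes tested. The fit of all probe sets gave 1634 changed at least 2-fold, 1550 lower and 84 higher. More were tested there, and 2-fold falls were more frequent among unnamed probe sets (6.72%) than among those with 1 gene (3.72%). These rates may not be comparable. Deviations from the group means correlated at r = 0.199, -0.00879 and -0.0333 between the same-numbered arrays 1, 2 and 3. Differently numbered arrays ranged from -0.171 to 0.191, so these values neither show nor exclude a pairing by number. With the replicate block 4926 genes were higher and 3820 lower, and among lists NK and cytotoxic markers gained a call (0.0436). Of the single genes, uncalled ACTB took a negative sign under repeated quantile normalization (-0.00398), cyclic loess (-0.163), centring (-0.156) and between arrays left out (-0.0362 to 0.0771), GAPDH under cyclic loess (-0.162) and centring (-0.0966), HSPA6 (-0.0168) and GNLY (-0.00781) under cyclic loess, and AFF1 (0.0818) and TSR1 (0.00307) a positive one under repeated quantile normalization. Camera called 8 lists without the dimmest genes, 9 above the median level and 0 with an estimated correlation, against 15; 6 lists (ATL genes, T-cell transcription factors, homologous recombination, G1/S, G2/M and the ZNF family) kept their call in all settings but the last. Their highest adjusted p over those settings was 0.0174, for G1/S genes. Against random lists matched on level and length, the G1/S list was the only 1 of these 6 without an adjusted value below 0.05 (0.1015). Without the dimmest genes the adjusted p was 0.0604 for anti-apoptotic, 0.0507 for p53 target, 0.0900 for transcriptional kinase, 0.0547 for ribosome biogenesis and 0.0824 for unfolded protein genes and 0.0832 for B-cell markers, and interferon genes changed sign (0.901). Above the median level these were 0.173, 0.172, 0.304, 0.198 and 0.325 for the same lists in that order, histones gained a call (0.0175), and uncalled lists changed sign: RNA polymerase II machinery (0.823), D-type cyclins (0.585), heat shock (0.657) and interferon genes (0.304). Camera compares a list with the other genes, and the transcriptional kinase and ribosome biogenesis lists have all members above the median level. For them these fits removed only other genes. Adjusted values against random lists matched on level and length were 0.320 for ribosome biogenesis, 0.243 for transcriptional kinase and p53 target, and 0.950 for histone genes. Repeated quantile normalization lost transcriptional kinases (0.235), B-cell (0.289) and myeloid markers (0.205), gained histones (0.0385) and changed the sign of RNA polymerase II machinery (0.970), D-type cyclins (0.933) and heat shock genes (0.975). Cyclic loess lost transcriptional kinases (0.182), B-cell (0.249) and myeloid markers (0.182), gained histones (0.0238) and changed the sign of D-type cyclins (0.954) and heat shock genes (0.9904). Array weights lost B-cell markers (0.0713). Centring lost ribosomal proteins (0.0565) and oxidative phosphorylation (0.0674) and changed the sign of glycolysis (0.847) and housekeeping genes (0.826). With an estimated correlation the adjusted p was 0.516 for ATL, T-cell transcription factor, p53 target, homologous recombination, G1/S, G2/M, ribosome biogenesis, unfolded protein, B-cell and myeloid lists, 0.535 for anti-apoptotic, 0.579 for transcriptional kinase and oxidative phosphorylation, 0.533 for ribosomal protein and 0.331 for ZNF genes. Fry, which asks whether a list's genes move on balance, also called T-cell receptor (0.0323), NF-kB (0.00721), pro-apoptotic (0.0142), RNA polymerase II (0.0255) and cytokine genes (0.00721), and fibroblast and epithelial (0.0323) and NK and cytotoxic markers (0.0272). With 1 array left out the range was 0.0416 to 0.160 for RNA polymerase II machinery, called without THZ1 replicate 2, 0.00546 to 0.0793 for oxidative phosphorylation, 0.0333 to 0.0942 for B-cell markers, 0.0314 to 0.156 for NK and cytotoxic markers, and 0.557 to 0.943 for glycolysis and 0.689 to 0.993 for housekeeping genes, both uncalled and of changing sign. Some of these ranges cross the threshold without DMSO replicate 1 or THZ1 replicate 2 (oxidative phosphorylation, NK and cytotoxic markers) or without DMSO replicate 2, DMSO replicate 3 or THZ1 replicate 1 (B-cell markers). Without counting the estimated correlation, the adjusted p over all alternatives ranged from 0.00409 to 0.173 for anti-apoptotic, 0.00162 to 0.172 for p53 target, 0.00612 to 0.304 for transcriptional kinase, 0.00217 to 0.198 for ribosome biogenesis, 0.00276 to 0.325 for unfolded protein, 6.18e-05 to 0.0565 for ribosomal protein, 0.000135 to 0.0793 for oxidative phosphorylation and 0.0175 to 0.426 for histone genes, and from 0.0172 to 0.289 for B-cell, 0.00641 to 0.205 for myeloid and 0.0272 to 0.348 for NK and cytotoxic markers. For the uncalled lists it reached 0.885 for T-cell receptor, 0.468 for NF-kB, 0.716 for pro-apoptotic, 0.984 for RNA polymerase II and 0.491 for cytokine genes and 0.557 for fibroblast and epithelial markers. Across the alternatives, named genes kept their direction and side of the threshold in 2116 comparisons, lost a call in 79 and gained one in 97.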

Other observations

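The gene classes and genes in the next 2 paragraphs were chosen after seeing the data. They describe which genes rose and are no independent test of these classes. Of 56 measured histone genes of the replication-dependent clusters, 26 rose and 3 fell (camera adjusted p = 0.000197 over 6 classes, and adjusted p = 0.266 with an estimated correlation), whereas the histone list fixed in advance was not called. Besides the histone genes named above, H2BC3 rose by 1.06 (SE 0.13) and H2AC11 by 0.88 (SE 0.13), while the linker histone genes H1-4 and H1-5 fell by 0.30 (SE 0.09) and 0.28 (SE 0.09). The counts were 30 rises and 3 falls after cyclic loess, 31 and 2 when quantile normalization was applied again and 18 and 8 after centring. Replication-dependent histone transcripts are short, lack introns and normally end without a poly(A) tail. Above the median level 24 of 48 histone genes rose, while 41.8% of all genes in the shortest of 10 length groups rose. The list fixed in advance had a median of 0.137, against 0.133 for random lists matched on level and length (adjusted value 0.950). The histone rises were thus not separated from those of short genes in general.

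The 19 genes at least 2-fold higher held 5 histone genes, 5 microRNA genes and 4 long non-coding RNA genes. Of 173 measured microRNA genes, 58 rose and 8 fell (camera adjusted p = 0.000350, and adjusted p = 0.381 with an estimated correlation). These counts were 23 and 17 after centring, 30 and 11 after cyclic loess and 35 and 10 when quantile normalization was applied again. The measured host genes of the largest risers were not called higher. MIR21 rose by 1.99 and its host VMP1 was not called at -0.02 (SE 0.10). MIR301A, which is dim, rose by 1.82 (SE 0.13) and its host SKA2 was not called at -0.03 (SE 0.10), and MIR15B rose by 1.38 (SE 0.09) while its host SMC4 fell by 0.33 (SE 0.09). MIRLET7I rose by 1.05 (SE 0.11). Probes for such short genes can read primary, precursor or mature forms, which were not separated. Small nucleolar RNA genes, which also lie within host genes, gave 23 rises and 28 falls among 175 (camera adjusted p = 0.808), 8 and 46 after centring, 28 and 34 after cyclic loess and 37 and 29 when quantile normalization was applied again. Long non-coding RNA genes had 214 rises and 46 falls among 626 (camera adjusted p = 0.000197, and adjusted p = 0.266 with an estimated correlation), but 49 and 67 after centring, 78 and 63 after cyclic loess and 113 and 48 when quantile normalization was applied again. Pseudogenes had 103 rises and 45 falls among 456 (camera adjusted p = 0.0437, and adjusted p = 0.198 with an estimated correlation), but 24 and 85 after centring, 54 and 57 after cyclic loess and 81 and 44 when quantile normalization was applied again. Above the median level lay 22 microRNA genes, 115 long non-coding RNA genes and 144 pseudogenes. There 15, 41 and 39 of them rose and 2, 23 and 28 fell. Most members of these classes were thus dim, and of all 9202 genes below the median level 3034 rose. Camera compares a class with the other genes, so its calls here were not separated from that rise of dim genes.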
